A study of Pimephales promelas with 16 samples.

How the data were processed

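Ovaries of fathead minnows (*Pimephales promelas*, a small freshwater fish used in ecotoxicology) were profiled on 16 two-colour oligonucleotide arrays. Per the labels, fish were held with no test compound, with 0.5 ug trenbolone (a synthetic androgen), with 500 ug flutamide (an androgen receptor antagonist) or with both, for 48 h. The labels give no volume for these amounts. Each of the 4 groups held 4 arrays, numbered as biological replicates, and each treatment tank held 6 fish. The number of tanks is not given, so fish from one tank cannot be told from fish of separate tanks. The sample was labelled with Cy5 on every array and a common reference pool of control fish with Cy3, with no dye swap.

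The scanner files deposited by the authors hold, in intensity units, the mean signal and the local background of each spot in each channel. They also hold intensity values processed by Agilent Feature Extraction. The file headers give its background subtraction and dye normalisation methods as codes (7 and 1). The labels name version 9.5 of that software and the headers version 9.1.3.1. The log10 ratio of processed sample over processed reference is a further column, and the deposited series table holds the same log10 ratio, rounded, with a largest difference of 0.005. The other deposited columns are flags of 0 or 1 set by the scanner software, such as signal well above background or saturation. The median log10 ratio per array in the authors' table lay between 0.0244 and 0.0915: 0.0244, 0.0452, 0.0483 and 0.0635 in control replicates 1 to 4, 0.0622, 0.0377, 0.0610 and 0.0775 in trenbolone, 0.0772, 0.0905, 0.0915 and 0.0508 in flutamide, and 0.0502, 0.0854, 0.0742 and 0.0792 in the mixture. Scale, centring and direction of that table were settled against the scanner files.

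Each array carried 44407 spots, of which 42990 were not controls, for 21495 distinct probes of 60 bases. The array names only 34 probes by a gene, under 33 gene names. None of its 6104 accessions matched the gene table used (0 matched), so all other probes are known by their code alone and genome positions were not analysed here. Array quality was summarised by the share of probes well above background, from 72.3% to 85.3% in the sample channel and from 75.2% to 81.7% in the reference channel. The median background-subtracted signal of an array ran from 153 to 610 in the sample channel and from 190 to 283 in the reference channel. Arrays give no counts, so their number limits the precision.

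The mean signals were background corrected by the normexp method with an offset of 50, normalised by loess within each array, and expressed as log2 of sample over reference. Spots marked by the scanner software as non-uniform or as population outliers were left out, and the spots of a probe were averaged. A probe was tested where its sample channel was well above background on at least 4 of the 16 arrays, whatever their group, which kept 18214 probes (84.7%). One linear model over the 4 groups was fitted with limma 3.58.1 (lmFit and moderated variances by eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading; figures were drawn with matplotlib 3.10.9. P values were adjusted by Benjamini-Hochberg over the probes tested, and a probe was called at an adjusted p under 0.05. All 6 pairs of groups were compared, and the interaction (mixture minus trenbolone minus flutamide plus control) asked whether the mixture departed from the sum of the single treatments on the log2 scale. All p values are two-sided.

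Of the 34 named probes, 21 were tested. The genes to name were set by a rule: for each treatment against control, up to 8 genes with the largest rise and 8 with the largest fall among called probes, filled up to 4 in each direction by smallest p where fewer passed, plus vitellogenin, zona pellucida, steroidogenic and gonadotropin receptor genes and the androgen and estrogen receptors where the array names them. For the other contrasts, the rule took the 4 named genes with the smallest p among those that pass. Other genes and coded probes named in the text were chosen after their values were seen. There were 21 gene lists for ovary, liver, muscle, blood and immune cells and for steroid synthesis, growth and stress, but only 1 reached the minimum of 3 tested genes. That list was tested with camera at a preset correlation of 0.01, and with an estimated correlation beside it. The contrasts, the rule for named genes, the lists and the alternative settings, apart from those named as chosen later, were fixed before the data were examined.

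Batches were read from the file headers: the arrays sat on 10 slides and were scanned on 4 days. Day 1 held control replicates 1 and 2 and trenbolone replicates 1 and 2; day 2 held replicate 3 of both groups. Day 3 held control 4, trenbolone 4, flutamide 1 and 2 and mixture 1 and 2; day 4 held flutamide 3 and 4 and mixture 3 and 4. Counts are given with scan day as a term of the model and within each day, most named genes are given with scan day as a term, and those given with group means, apart from FSHR, also within days. Where a day held a single array of a group, that array was assumed to vary like the other groups of the day.

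On 4 arrays (control 1, control 2, trenbolone 4 and mixture 1) the normexp fit was pulled down most strongly by a few spots far dimmer than their local background. The fitted background means in the sample channel were -157, -508, -737 and -722 on these arrays, although only 6, 5, 11 and 8 spots lay below their local background. The first principal component held 42.0% of the variance, and the split of those 4 arrays from the others accounted for a share of 0.93 of it. After a refit without such spots the background means were 3.43, 12.7, 4.27 and 6.24 and the first component held 14.9%. Each taken alone, scan day then accounted for a share of 0.72 of that component, the treatment group for 0.40 and the split of those 4 arrays for 0.13. On flutamide 1, flutamide 3 and mixture 4 the fitted sample-channel means were also below 0, at -33.9, -5.01 and -4.02. The refit gave 5.55, 3.12 and 0.0759 there. The values fixed beforehand were kept as the main values, and the refit, chosen after seeing the data, is given beside them for the called probes and for most of the named genes.

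The other alternatives used the processed signals, no background subtraction, median centring, Aquantile scaling, the sample channel alone, the authors' table, other filters, array weights, other variance priors, an unmoderated test, blocks for replicate number, slide and scan day, fits of only the groups compared, and each array left out in turn. Shifts were added to simulated normal noise with the fitted spread of each probe, to see what the design recovers. That noise held no scan-day effect, no fault shared by arrays and no correlation between probes, so the real arrays may recover fewer. Of 100 probes shifted by a log2 of 1, 66 were called in trenbolone against control, 68 in flutamide against control and 37 in the interaction; with scan day in the model 60, 37 and 21 were called. Of 100 shifted by a log2 of 2, 85, 94 and 81 were called, and 88, 85 and 76 with scan day in the model.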

Results

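Gene expression was measured in the ovaries of fathead minnows after 48 h with 0.5 ug trenbolone, with 500 ug flutamide, with the mixture of both, or with neither, on 4 arrays per group. Each value is the log2 ratio of an ovary over a common reference pool made from control fish, and group values are given with the SD over 4 arrays unless another number is stated. The sample channel was well above background at 72.3% to 85.3% of probes per array, and 18214 of 21495 probes were tested. The array names 34 probes by gene, of which 21 were tested, so the account by gene rests on those 21. The array names no vitellogenin, star, aromatase or other steroidogenic gene, androgen receptor or luteinising hormone receptor.

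Trenbolone against control asked what the androgen alone did in the ovary. A probe with no gene name, EA_Pp_61588, rose in trenbolone ovaries, from -0.33 ± 0.20 in controls to 0.51 ± 0.069, and all 4 trenbolone arrays lay above every control array. Its 60-base sequence is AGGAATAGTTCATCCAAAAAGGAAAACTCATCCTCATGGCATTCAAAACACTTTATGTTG, and it was named after its values were seen. None of the 21 named genes passed the test (0 of 21; 0 adjusted over the list alone). The lowest p values among those with lower means belonged to cytochrome b, a mitochondrial subunit of the respiratory chain, at -3.29 ± 0.29 against -2.70 ± 0.42 in controls, and to alpha amylase, a starch-digesting enzyme, at -2.87 ± 0.79 against -1.92 ± 1.30. Myoblast determination protein, a muscle transcription factor, had the lowest p among those with higher means, at 0.79 ± 0.46 against 0.18 ± 0.49.

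The rise of EA_Pp_61588 was a log2 fold change of 0.84 (SE 0.11; limma adjusted p = 0.0399), and it was the only probe called of 18214, with 435 at an unadjusted p under 0.05. The log2 fold change was again 0.84 (SE 0.11) with scan day in the model, which leaves fewer degrees of freedom, and with an adjusted p of 0.198 the call ended. The refit of the background gave 0.93 (adjusted p = 0.00527, and 0.0425 with scan day in the model). In the sample channel alone the probe differed by 1.01 and in the reference channel alone by 0.13. For the named genes the log2 fold changes were -0.58 (SE 0.27) for cytochrome b, -0.96 (SE 0.59) for alpha amylase and 0.60 (SE 0.30) for myoblast determination protein, with limma adjusted p values of 0.99985 over all probes and, over the list alone, of 0.701 for cytochrome b and myoblast determination protein. Lamin B1, a protein of the nuclear lamina, was at -0.26 (SE 0.52) and follistatin, an activin-binding protein, at -0.08 (SE 0.19). On the side of higher means stood the leukocyte integrin CD18 type 2 at 0.11 (SE 0.12), adenosine deaminase, an enzyme of purine breakdown, at 0.16 (SE 0.34), and the transcription factor myocyte enhancer factor 2a at 0.03 (SE 0.10). The refit of the background gave 0.77 for myoblast determination protein, -0.81 for alpha amylase, -0.41 for lamin B1, 0.04 for CD18 type 2, 0.07 for adenosine deaminase and 0.06 for myocyte enhancer factor 2a. Scan day in the model left all these differences as they were, since the groups shared days evenly.

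Within scan days the cytochrome b difference was -0.99 on day 1, -0.47 on day 2 and 0.12 on day 3, the last 2 days with 1 array per group. Alpha amylase differed by -2.0, 1.01 and -0.83 on the same days, and myoblast determination protein by 0.52, 1.75 and -0.39, so none of the 3 held one direction. After the refit of the background cytochrome b differed by -0.53, -0.47 and -0.72 and myoblast determination protein by 0.56, 1.76 and 0.19 on those days, each in one direction, and alpha amylase by -0.92, 1.04 and -2.45. Within day 1 no probe was called by limma (0, with 3448 of 18187 at an unadjusted p under 0.05, and 0 with 721 after the refit). Day 3 set 1 array against 1, with the spread taken from the other groups, so its count decides little (0, with 745 of 18191, and 1155 after the refit), and day 2 allowed no test.

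**Figure D1:**
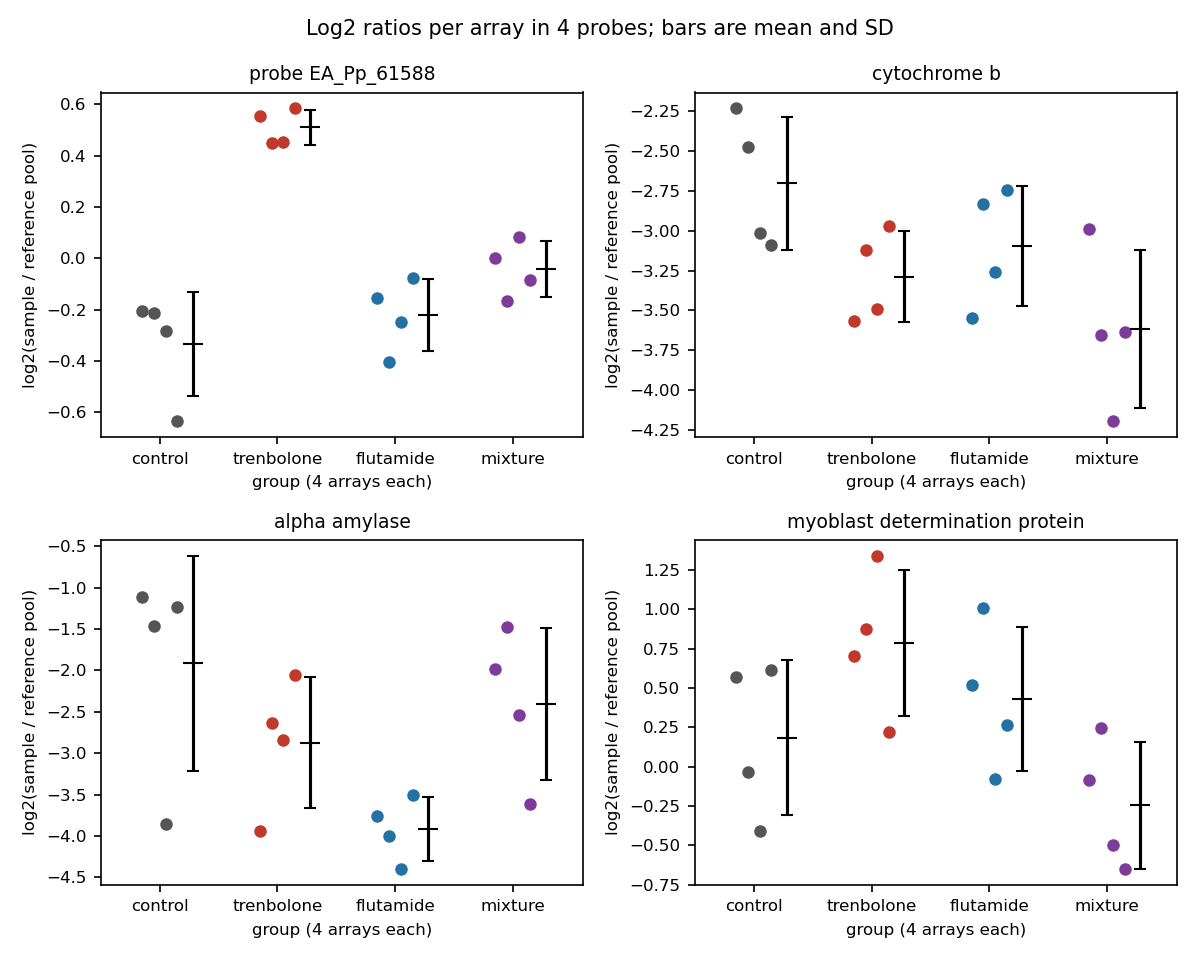
Log2 ratios of ovary over reference pool (vertical axes) for EA_Pp_61588, cytochrome b, alpha amylase and myoblast determination protein in the 4 groups (horizontal axes); points are arrays, bars the mean and SD of 4 arrays. EA_Pp_61588 averaged 0.51 in trenbolone and -0.33 in control ovaries, with no overlap, whereas the groups overlap in cytochrome b, where the mixture averaged -3.62 and controls -2.70.

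Flutamide against control asked what the antiandrogen alone did. Alpha amylase averaged -3.92 ± 0.38 in flutamide ovaries and -1.92 ± 1.30 in controls, where control replicate 3 stood at -3.85, within the range of the flutamide arrays. After the refit control replicate 2 lay within that range too, at -3.51. The follicle-stimulating hormone receptor FSHR, which receives the pituitary signal for follicle growth, was above background on all 4 flutamide arrays and on 0 control arrays, with signals of 62.8 ± 3.78 and 46.2 ± 12.0 scanner units. Lamin B1 averaged -0.47 ± 0.69 against 0.32 ± 0.48. None of the 21 named genes passed the test (0 of 21; 0 adjusted over the list alone).

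The log2 fold change of alpha amylase was -2.0 (SE 0.59; limma adjusted p = 0.461, and 0.0948 over the list alone), and -2.40 with scan day in the model; within day 3, the only day with both groups, it was -2.65 (lamin B1 -1.30). FSHR was 1.14-fold higher than control by its normalised sample-channel signal, which includes the offset of the background correction. The offset shrinks this fold, so it is not the ratio of the scanner signals given above. FSHR lay near the floor, and the fold gives no lower bound. Its fitted log2 difference, 0.18 (limma adjusted p = 0.515) or 1.01 with the processed signals (0.378), depends on the handling of the background and measures no exact change, because FSHR was not above background on any control array nor in the reference channel on any array. Lamin B1 differed by -0.80 (SE 0.52), cytochrome b by -0.39 (SE 0.27) and the taurine transporter by -0.37 (SE 0.32). Higher means were found for the activin receptor ACTRIIB at 0.17 (SE 0.15), adenosine deaminase at 0.37 (SE 0.34) and myocyte enhancer factor 2a at 0.11 (SE 0.10). With scan day as a term the values were -0.56 for lamin B1, -0.26 for cytochrome b, -0.46 for the taurine transporter, -0.06 for ACTRIIB (the other direction), 0.24 for adenosine deaminase and 0.08 for myocyte enhancer factor 2a. From the background refit came -1.49 for alpha amylase, -0.81 for lamin B1, -0.17 for cytochrome b, -0.03 for the taurine transporter, 0.02 for ACTRIIB, 0.08 for adenosine deaminase and 0.08 for myocyte enhancer factor 2a. Across all probes limma called 0 in either direction, with 1709 of 18214 at an unadjusted p under 0.05 where 5% would be 911. With scan day in the model that number was 615, and within day 3 (2 flutamide arrays, 1 control) it was 568 of 18206, with 0 called each time. The refit gave 2150, 786 with scan day in the model (1 called) and 995 within day 3 (0 called).

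**Figure D2:**
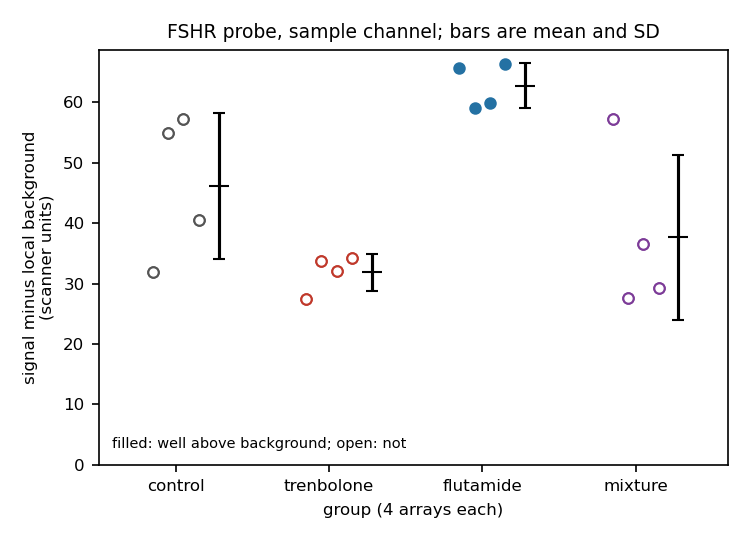
Sample-channel signal of the FSHR probe minus its local background, in scanner units (vertical axis), on the 4 arrays of each group (horizontal axis); filled points were well above background, open points were not, and bars are mean and SD. The 4 flutamide arrays, from 59.1 to 66.4, were the only filled points, and the highest array of the other groups stood at 57.2.

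Mixture against control asked what both compounds together did. Cytochrome b averaged -3.62 ± 0.49 in mixture ovaries and -2.70 ± 0.42 in controls, the smallest p of the named genes in this comparison. Adenosine deaminase averaged 1.64 ± 0.78 against 1.02 ± 0.48, lamin B1 -0.44 ± 1.26 against 0.32 ± 0.48 with mixture replicate 3 alone at -2.28, and myoblast determination protein -0.25 ± 0.40 against 0.18 ± 0.49. None of the 21 named genes passed the test (0 of 21; 0 adjusted over the list alone).

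The log2 fold change of cytochrome b was -0.91 (SE 0.27; limma adjusted p = 0.694, and 0.0856 over the list alone). After the refit of the background it was -0.85 (SE 0.22; adjusted p = 0.233), and cytochrome b then passed over the list alone with 0.0355. It was -0.78 (SE 0.39) with scan day in the model, and within day 3 it was -0.23 between 2 mixture arrays and 1 control, and -0.57 there after the refit. The other log2 fold changes were 0.61 (SE 0.34) for adenosine deaminase, -0.77 (SE 0.52) for lamin B1, -0.43 (SE 0.30) for myoblast determination protein, -0.49 (SE 0.59) for alpha amylase, 0.14 (SE 0.15) for ACTRIIB, 0.05 (SE 0.10) for myocyte enhancer factor 2a and 0.11 (SE 0.27) for pentraxin, an acute-phase protein. Without mixture replicate 3 the difference of lamin B1 was -0.15. Within day 3 adenosine deaminase differed by -0.27, the other direction (0.13 after the refit), lamin B1 by -0.90 and myoblast determination protein by -0.53. Adding scan day to the model gave 0.48 for adenosine deaminase, -0.53 for lamin B1, -0.03 for myoblast determination protein, -0.88 for alpha amylase and 0.02 for myocyte enhancer factor 2a, and turned ACTRIIB to -0.09 and pentraxin to -0.07. The background refit gave 0.51, -0.81, -0.56, -0.38, 0.07, 0.08 and 0.17 for these 7 genes in the same order. Across all probes limma called 0, with 880 at an unadjusted p under 0.05; with scan day in the model it called 0 with 462, and within day 3 it called 0 with 675 (1038 after the refit).

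The refit of the background raised the count for the mixture against control to 11 probes, 1 higher and 10 lower, with 1868 at an unadjusted p under 0.05. Among them, EA_Pp_56703 fell by a log2 of 1.31 and EA_Pp_65810 rose by 0.71 (limma adjusted p = 0.0458 for both); neither has a gene name, and both were picked after their values were seen. With scan day added to the refit none of these 11 passed, at adjusted p values from 0.178 to 0.727, and 1 other probe was called, higher in the mixture. The differences themselves were -1.05 (SE 0.23, from 0.21) for EA_Pp_56703 and 0.70 (SE 0.18, from 0.12) for EA_Pp_65810, so the first became smaller, the other kept its size, and the errors grew.

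Among the genes of sex steroid and egg biology, estrogen receptor alpha differed from control by -0.10 with trenbolone (95% interval -1.08 to 0.87), -0.41 with flutamide (-1.39 to 0.57) and -0.34 with the mixture (-1.31 to 0.64). These values were 0.03, 0.00 and -0.22 (SE 0.22 each) after the refit of the background, and -0.10, -0.33 and -0.25 with scan day in the model. Estrogen receptor beta differed by 0.03, 0.00 and 0.02, by 0.03, 0.09 and 0.10 with scan day in the model, and by -0.13, -0.19 and -0.13 after the refit; its reference signal was above background on 5 of 16 arrays, so these ratios depend on the handling of the background. Zona pellucida glycoprotein 3, an egg envelope protein, differed by -0.18, -0.46 and 0.11 with 3 usable arrays in each treated group (SE 0.56 each), and by -0.26, -0.32 and 0.26 with scan day in the model. The value with flutamide rested on flutamide replicate 4, at -1.16, and was 0.44 without it, in the other direction. Cyclin B1, a regulator of entry into M phase, differed by 0.01, -0.03 and 0.03 (SE 0.23 each), and by 0.01, -0.31 and -0.25 with scan day in the model. None of these 4 genes passed in limma in any of the 3 comparisons.

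In the list of gonadotropin and growth factor signalling, 3 of 4 named genes were tested and 0 of the 3 passed in any comparison. Inhibin, a gonadal hormone that lowers follicle-stimulating hormone, differed from control by 0.07 with trenbolone, 0.18 with flutamide and -0.18 with the mixture (SE 0.30 each); without flutamide replicate 4, at 0.59, the value for inhibin with flutamide was -0.11. The background refit gave 0.14, 0.27 and -0.25. Follistatin differed by -0.08, -0.13 and -0.02 (SE 0.19 each), and after the refit by -0.08, -0.05 and 0.11, the last in the other direction. FSHR was not above background on any control, trenbolone or mixture array, so no difference between those groups was measured. As a set in camera the list had p = 0.885, 0.281 and 0.633 in these comparisons and was not called in any of the 7 contrasts; the lowest value was p = 0.0666 for mixture against flutamide, and p = 0.228 there with an estimated correlation. Of the other lists, steroid receptors held the 2 estrogen receptors, egg envelope held zona pellucida glycoprotein 3, meiosis and cell cycle held cyclin B1, and immune cells held complement C3S and 2 probes of invariant chain like protein 1. Lamin B1 and desmoglein1 entered the lists of extracellular matrix and of muscle by their spelling alone. The lists for steroid synthesis, yolk precursors, oocyte markers, xenobiotic metabolism, oxidative stress, chaperones, cholesterol, ribosomal proteins, oxidative phosphorylation, the proteasome, apoptosis, testis, blood cells and liver proteins matched 0 named genes each. Matching went by spelling and also missed genes. Cytochrome b did not enter oxidative phosphorylation, complement C3S did not enter liver proteins and myoblast determination protein did not enter muscle.

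Mixture against trenbolone, mixture against flutamide and the interaction asked whether the compounds modified each other. Myoblast determination protein averaged 0.79 ± 0.46 with trenbolone alone and -0.25 ± 0.40 with the mixture. Alpha amylase averaged -3.92 ± 0.38 with flutamide alone and -2.40 ± 0.92 with the mixture. EA_Pp_61588, the probe that rose with trenbolone, was lower by 0.55 (SE 0.11) in the mixture than with trenbolone alone (limma adjusted p = 0.769). It was higher than control by 0.29 (SE 0.11; adjusted p = 0.931). All 4 mixture arrays lay below every trenbolone array and above every control array, but neither difference passed after adjustment over all probes. The probe was picked for its gap between trenbolone and control, which favours a mixture value between them. Its interaction was -0.66 (adjusted p = 0.999). None of the 21 named genes passed in these contrasts (0 over all probes; 0 adjusted over the list alone), and the following genes were chosen after their values were seen.

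Myoblast determination protein differed by -1.03 (SE 0.30) between mixture and trenbolone, with a limma adjusted p of 0.0870 over the list alone. The refit of the background gave a difference of -1.32, with an adjusted p over the list alone of 0.0189, and with the processed signals -2.28 and 0.0181. With scan day in the model it was -0.63 (SE 0.39), and within day 3 -0.14, or -1.01 after the refit. Between mixture and flutamide it differed by -0.68 within day 3 (-0.98 after the refit) and by -0.67 within day 4. Its interaction was -1.28 (SE 0.43; 0.112 over the list alone), and -2.88 (0.0435 over the list alone) with the processed signals. After the refit 0 of the 21 named genes passed over the list alone in the interaction. Alpha amylase differed by 1.51 (SE 0.59) between mixture and flutamide, by 2.16 within day 3 (1.32 after the refit) and by 0.87 within day 4, and its interaction was 2.47 (SE 0.84; adjusted p = 0.112 over the list alone). FSHR was above background on the flutamide arrays and on 0 of the mixture arrays. It was 1.18-fold lower in the mixture than with flutamide by its normalised sample-channel signal, which includes the offset. That signal lay near the floor, and the limma test did not pass (adjusted p = 0.993).

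Across all probes limma called 0 in mixture against trenbolone (482 at an unadjusted p under 0.05), 0 in mixture against flutamide (768) and 0 in the interaction (449). With scan day in the model it called 0 in each, with 261, 777 and 495. Within day 3 the counts were 0 with 232, 590 and 384, and 0 with 1138, 755 and 1098 after the refit. Within day 4 mixture against flutamide gave 0 with 1012, or 1002 after the refit. Flutamide and mixture arrays of the same number shared a slide. With slide in the model mixture against flutamide gave 0 with 878, or 1105 after the refit.

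Trenbolone against flutamide set the androgen beside the antiandrogen. FSHR, above background on 0 trenbolone arrays, was 1.20-fold lower with trenbolone than with flutamide by its normalised sample-channel signal, which includes the offset. That signal lay near the floor, and the limma test did not pass (adjusted p = 0.634, and 0.596 over the list alone). Alpha amylase was at 1.04 (SE 0.59), with 1.44 once scan day was in the model and 0.68 after the refit. Myoblast determination protein was at 0.36 (SE 0.30), with -0.04 and 0.50 under the same settings. EA_Pp_61588 was at 0.73 with an adjusted p of 0.0508. None of the 21 named genes passed (0 over all probes; 0 adjusted over the list alone), and across all probes limma called 0, with 1368 at an unadjusted p under 0.05, 516 with scan day in the model and 730 within day 3 (941 there after the refit). After the refit of the background 3 probes were called, EA_Pp_65365 at 1.97, EA_Pp_57868 at -1.40 and EA_Pp_61588 at 0.73 (adjusted p = 0.0341), and 0 with scan day added (1068 at an unadjusted p under 0.05), where they stood at 1.69, -1.03 and 0.72 with larger errors; none of the 3 has a gene name, and they were named after their values were seen.

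Across the 18214 probes, which are not independent replicates, the log2 fold changes against the shared controls correlated at r = 0.45 between trenbolone and flutamide, 0.61 between trenbolone and the mixture and 0.63 between flutamide and the mixture. Unchanged groups were simulated by centring the arrays within their groups and shuffling all of them, with a drawn control group shared by the treatments. The real control arrays were not kept as controls, so faults of single control arrays were not held fixed. These simulated groups gave medians of 0.53, 0.46 and 0.54, and 67, 32 and 32 of 100 draws were as high. The covariances were 0.0432, 0.0444 and 0.0729, and in the simulation 0.0431, 0.0366 and 0.0386. When each treatment was set against another pair of controls the correlations averaged -0.01, -0.00 and 0.17, with both signs among the choices of pairs. After the refit they averaged 0.00, 0.12 and 0.14, above 0 in every choice for trenbolone and the mixture (0.05 to 0.18) and for flutamide and the mixture (0.06 to 0.27). The correlations against all 4 controls were 0.49, 0.59 and 0.68 with scan day in the model, and 0.30, 0.43 and 0.69 with scan day after the refit. The simulation and the choices of control pairs ignore scan day. All flutamide and mixture arrays were scanned on days 3 and 4, and of the controls only replicate 4 was. The values therefore do not separate shared days from shared effects.

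Among probes chosen on trenbolone against 2 of the controls (unadjusted p under 0.01, between 57 and 212 probes over 6 choices), 52.6% lay nearer to the other 2 controls in the mixture than with trenbolone, with a range of 40.7% to 61.4%. Unchanged groups gave 67.2% on average, with a range of 50.7% to 80.8%, so the real share was not above their average. They were shuffled without regard to scan day and held no trenbolone effect to reverse. Trenbolone shared days evenly with the controls. All mixture arrays were scanned on days 3 and 4, and of the controls only replicate 4 was. A day effect could therefore move the mixture away from control, so these values do not decide whether it returned towards control. Over all tested probes the share was 42.2% against the other controls.

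Of the named probes that were not tested, too few arrays were above background. In the sample channel the gonadotropin-releasing hormone GnRH-III, JAK3, nebulin, polyA polymerase, reticulocalbin 3, G coupled protein receptor kinase 7, the Na K ATPase alpha subunit 3 and one probe of invariant chain like protein 1 were above background on 0 of 16 arrays. Inhibin beta b was above it on 2, desmoglein1 on 1, and glutamic acid decarboxylase isoform 67, traf2 and the other probe of invariant chain like protein 1 on 3. No difference in these genes was detectable at this signal.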

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

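The tests of array brightness, slide and scan day for FSHR, those of scan day and exposure for the flutamide probes, and all values from the background refit were chosen after the result was seen; the counts of other splits of the arrays were planned.

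FSHR, the receptor for follicle-stimulating hormone, was well above background on all 4 flutamide arrays and on 0 of the other 12, with a signal of 62.8 ± 3.78 (SD, n = 4) with flutamide against 46.2 ± 12.0 in controls, 31.9 ± 3.06 with trenbolone and 37.6 ± 13.6 with the mixture. It was 1.14-fold higher than control, 1.20-fold higher than trenbolone and 1.18-fold higher than the mixture by the normalised signal of 1 channel. There was no dye swap. That normalised signal includes the offset of the background correction, which shrinks the folds, so they are not ratios of the scanner signals above. These folds are no lower bounds. Brighter flutamide arrays stay open: 6 arrays of the other groups had a larger share of probes above background than the flutamide array with the smallest share, but FSHR lay near the floor, which excludes nothing. Scan day or slide stays open too: the 4 slides of the flutamide arrays also held the mixture arrays, but the pattern itself fixed that count. Chance cannot be excluded: 9 of 100 drawn sets of 4 arrays had as many probes above background on those arrays alone, with 1 for flutamide and 4 in the highest other set, and an effect of flutamide stays open as well.

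Flutamide against control had 1709 probes at an unadjusted p under 0.05, where 5% of 18214 is 911, and limma called 0. Scan day may account for the excess: in the reference channel alone, which carries the same pool on every array, 2180 probes passed the same threshold. With scan day in the model 615 did, but that term also costs precision. In simulated noise with no day effect it cut the flutamide shifts of a log2 of 1 that were called from 68 to 37 of 100. The fall to 615 therefore does not tell the 2 sources apart. Flutamide exposure cannot be told apart from scan day here, because 1 control array shared a day with flutamide arrays. Within that day 568 of 18206 probes passed, and 995 after the refit, with 3 arrays of the 2 groups and the spread taken from all 6 arrays of the day, so the count lies on either side of 5%.

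Chance could not be excluded for the count of 1 in trenbolone against control, EA_Pp_61588, since 4 of the 35 splits of those 8 arrays gave a count as large, with 1 in the highest other split. With counts of 0, all 35 of 35 splits were as large in flutamide against control (highest other 7), mixture against control (highest other 8), mixture against trenbolone (highest other 0), mixture against flutamide (highest other 1) and trenbolone against flutamide (highest other 0), and all 100 of 100 drawn assignments in the interaction, but a real count of 0 fixes those shares, so they say nothing about chance. A drawn assignment for the interaction called 4231 probes, so groupings other than the treatments can give many calls. The source of that count was not tested. In these values the background fit set control 1, control 2, trenbolone 4 and mixture 1 apart, a split that accounted for a share of 0.93 of the first principal component. After the background refit, mixture against control called 11 probes, and 1 of 35 splits, the real one, gave as many, with 2 in the highest other, so chance could be excluded only if arrays are exchanged freely; that exchange ignores scan day, and 1 of 35 is the least it can give. With scan day in the model as well, none of these 11 passed (adjusted p from 0.178 to 0.727). Their differences did not all shrink: EA_Pp_68582 stayed at -1.07 (SE 0.16, then 0.23), EA_Pp_57032 went from -0.93 to -0.61 and EA_Pp_55677 from -0.67 to -0.81. The lost calls therefore do not settle whether scan day was their source.

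In 5 of 97 groups of 4 arrays one array stood far from the other 3 (gap over the group's range above Dixon's 95% critical value), where chance alone gives about 4.85. Alpha amylase in controls had a ratio of gap to range of 0.869, with control replicate 3 at -3.85 and the others from -1.47 to -1.11; after the refit of the background control replicates 2 and 3 stood at -3.51 and -3.88 and the others at -1.24 and -1.23. Estrogen receptor alpha with flutamide had 0.875, with flutamide replicate 4 at -0.86 and the others from -1.99 to -1.85. Estrogen receptor alpha with the mixture had 0.857, with mixture replicate 1 at -0.50 and the others from -2.02 to -1.81. The taurine transporter with the mixture had 0.914, with mixture replicate 1 at -0.43 and the others from -1.51 to -1.42. After the refit of the background mixture replicate 1 stood at -1.85 for estrogen receptor alpha and at -1.16 for the taurine transporter. The median signal of the sample channel in trenbolone had 0.849, with trenbolone replicate 2 at 166 and the others from 266 to 284.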

How the results depend on the processing

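The background refit (alone or with a block), the fit with 4 arrays left out, the estimated correlation for list calls, and the values of these for named genes were chosen after the result was seen; the other alternatives were planned. In trenbolone against control the call of EA_Pp_61588 held in 12 of 37 alternatives, with a positive difference in all 37, from 0.74 to 1.43, and adjusted p from 0.00467 to 0.99997. Of those 12, Aquantile scaling leaves the log2 ratios as they are. Its result (0.84, limma adjusted p = 0.0399) and its values for named genes were therefore fixed in advance. The highest difference, 1.43, came from the slide block. In these 2 groups, all arrays but control replicate 4 and trenbolone replicate 4 had a slide to themselves. With slide as a block, alone or with the refit, the comparison therefore rested on those 2 arrays, and its results decide little. Limma called 0 probes in that comparison with the processed signals (989 at an unadjusted p under 0.05), median centring, the authors' table, the filter on all 16 arrays, only the 2 groups compared, the replicate block, the slide block (2890), the scan day block (521) and the refit with slide block (963), and the unmoderated test also gave 0. It called 2 (1 higher, 1 lower) with array weights and 3 (2 higher, 1 lower) with 4 arrays left out. Each array left out in turn gave 0 to 5, with 5 without trenbolone replicate 4, 1 without flutamide replicate 2 and 0 in the other 14.

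An unadjusted p under 0.01 with a fold of at least 1.5 gave 56 probes for trenbolone, 207 for flutamide and 117 for the mixture against control, 70 for mixture against trenbolone, 120 for mixture against flutamide, 202 for trenbolone against flutamide and 81 for the interaction.

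Flutamide against control gave 1 lower with the sample channel alone and 1 higher with the refit and scan day block, and 0 to 1 with an array left out (1 without flutamide replicate 3). Mixture against control gave 3 lower without background subtraction, 2 lower with the replicate block, 11 (1 higher, 10 lower) with the background refit, 1 higher with the refit and scan day block and 16 lower with the refit and replicate block; leaving out an array gave 0 throughout. Mixture against trenbolone gave 4 (3 higher, 1 lower) with 4 arrays left out, and 0 to 4 with an array left out: 4 without trenbolone replicate 4, 2 without mixture replicate 1 and 1 without mixture replicate 2.

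Mixture against flutamide gave 1 lower with the filter on all 16 arrays, with trend and robust, with the replicate block and with the refit and replicate block, 12 (4 higher, 8 lower) with array weights and 1 higher with 4 arrays left out. Leaving out an array gave 0 to 4: 4 without mixture replicate 1, and 1 without control replicate 2, 3 or 4 or flutamide replicate 1. In trenbolone against flutamide, probes changed were 4 (3 higher, 1 lower) without background subtraction, 3 (2 higher, 1 lower) with the filter on all 16 arrays and with the background refit, 9 with only the 2 groups compared, 89 (43 higher, 46 lower) with array weights and 4 (2 higher, 2 lower) with 4 arrays left out. Leaving out an array gave 0 to 5: 5 without flutamide replicate 2, 3 without control replicate 4, mixture replicate 1 or trenbolone replicate 4, 2 without control replicate 1 or 3 and 1 without flutamide replicate 3. The interaction gave 1 lower with the refit and replicate block and 1 higher with 4 arrays left out. The unmoderated test and the fit of only 2 groups were not planned for it. The cause of these differences was not tested.

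The gene list was called in 1 contrast with the processed signals (trenbolone against flutamide, adjusted p = 0.0490) and 1 with the sample channel alone (the same contrast, 0.0313), and in 0 to 1 with an array left out: in mixture against flutamide without flutamide replicate 1, flutamide replicate 3 or mixture replicate 1. With an estimated correlation these 5 calls were lost, at p = 0.186, 0.122, 0.172, 0.122 and 0.130. Of 772 alternative values of named genes in each comparison with control, 0 passed in limma over all probes, and 110, 104 and 106 had the other sign in trenbolone, flutamide and mixture. The correlations between treatments and the share nearer to control moved by less than their spread in every alternative run; with the processed signals, the authors' table and the filter on all 16 arrays no called probe was left to measure a return towards control. Of 24 same-number pairs of arrays 10 correlated over 0.1 (2 after the refit); in flutamide and mixture the same number also marks a shared slide and scan day. Signal over background limits the 13 named probes that were not tested. Correlations between arrays ran from 0.81 to 0.95, and from 0.89 to 0.95 after the background refit.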

Other observations

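The test of other tissues in the reference pool was chosen after the result was seen; that of dye bias was planned.

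Apart from the treatments, the ratios over the reference pool show which named genes the ovaries held in larger or smaller amounts than the pool (scanner-processed signals, SD over 16 arrays). Of the named genes tested, adenosine deaminase stood highest in the ovaries, at a log2 ratio of 2.45 ± 0.37. Zona pellucida glycoprotein 3, an egg envelope protein, stood at 1.47 ± 0.72 (n = 13), the activin receptor ACTRIIB at 1.30 ± 0.24 and the leukocyte integrin CD18 type 2 at 1.07 ± 0.17. Cyclin B1 stood near the pool, at 0.05 ± 0.29. The values with the offset of 50 were smaller, at 1.31, 0.98, 0.45 and 0.31 for adenosine deaminase, zona pellucida glycoprotein 3, ACTRIIB and CD18 type 2. Estrogen receptor beta was above background in the ovaries on 15 arrays and in the pool on 5, so no exact ratio is given.

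On the other side, complement C3S, a complement protein made mainly in the liver, stood at -6.15 ± 0.49 and below 0 on all 16 arrays. Alpha amylase, an enzyme of the digestive system, stood at -3.07 ± 1.18, cytochrome b at -2.98 ± 0.44, estrogen receptor alpha at -2.07 ± 0.50 and the taurine transporter at -1.12 ± 0.30, each below 0 on all 16. With the offset these were -6.17, -2.78, -3.18, -1.46 and -1.17. The reference exceeded the sample over 4 times at 1993 tested probes, and the sample exceeded the reference over 4 times at 605. There were 116 probes above background in the reference on all 16 arrays and in the sample on none, and 32 the other way round.

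A hypothesis is that the reference pool held RNA of other tissues than ovary, as its label gives tissue of control fish and the sample labels give gonadal tissue. Complement C3S stood at -6.14 ± 0.30 in the 4 control ovaries, so treatment cannot account for its ratio, but these arrays are among those that prompted the hypothesis. A dye bias common to bright probes is argued against as the whole cause, since the 104 tested probes nearly as bright in the reference had a median ratio of -1.38. Of these, 19 had a lower ratio than complement C3S, down to -9.27. A dye bias of single probes cannot be told without a dye swap. RNA of other tissues in the pool stays open, as the ratio in control ovaries cannot decide it. Pentraxin, an acute-phase protein, stood on the other side at 0.79 ± 0.45, and the list for liver and plasma proteins matched 0 gene names on the array by spelling.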
